A study of Mus musculus with 18 samples.

How the data were processed

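RNA was measured in mouse oocytes from 5-week-old females in which the gene for VPS34, the class III phosphatidylinositol 3-kinase encoded by Pik3c3, carried loxP sites. In the conditional knockout (cKO) a Zp3-Cre transgene, which is active in growing oocytes, deletes the floxed part of the gene, and the control mice carried the floxed gene without Cre. Fully grown oocytes at the germinal vesicle (GV) stage were collected 46 h after PMSG, a hormone that stimulates follicle growth. Ovulated oocytes arrested at metaphase II (MII) were collected 14 h after hCG, the hormone that triggers ovulation. Each library was made from 5 oocytes by Smart-seq2 with ERCC spike-in RNAs and the KAPA HyperPlus kit, per the labels' protocols. The series has 18 samples in 6 groups, of which 12 samples in 4 groups (GV and MII, control and cKO, 3 libraries each) entered the comparisons. The 6 samples of 2-cell embryos are not analysed here.

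The authors deposited a table of whole-number read counts per gene symbol, not normalized, with 1 column per library. It has 55383 entries, of which 92 are ERCC spike-ins and 55291 are genes. fastp, HISAT2, featureCounts and the mouse genome build mm10 are named, without versions, per the submitters' processing notes. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads that a gene shares with a near-identical copy could therefore have been split or dropped, and members of multigene families are marked as uncertain in the text. For the same reason, reads of overlapping genes on opposite strands cannot be assigned with certainty.

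Columns were matched to samples by name. The names of the 12 columns used carry the age, the stage, a letter and the replicate number. The letter C was read as the control arm and T as the test (Cre) arm, although the sample titles use neither letter. The Pik3c3 counts had been seen when this reading was written down, so the low Pik3c3 counts of the cKO columns are no independent check of it. Every direction of a genotype difference rests on this reading. Another 6 columns carry names that match no label and were not used in any step.

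Gene totals ranged from 2609780 to 4696630 counts per library, and spike-in counts were left out of the library sizes except where stated. Groups of 3 limit what can be seen: an exact permutation test of 3 against 3 libraries cannot go below p = 0.1. The series describes the replicates as biological, and no label used here ties libraries to individual animals. If libraries shared an animal or a collection, p-values would measure a narrower spread than that between animals. Smart-seq2 reads carry no molecular identifiers, so counting intervals and limits from a count of 0 cover counting error only. Limits use a floor of 3 counts over the group.

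Genes were tested with edgeR 4.0.16 in R 4.3.3. Counts were scaled by TMM, genes were kept by filterByExpr, the negative binomial model was fitted with robust quasi-likelihood (glmQLFit, glmQLFTest), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The genotype comparison at each stage used the 6 libraries of that stage. The change from GV to MII in each genotype, and the difference of these changes (the interaction), came from 1 fit of all 12 libraries. This fit had been designed for 18 libraries. Standard errors of log2 fold changes are the fold change divided by the root of its F statistic. CPM values given with an SD are scaled to the gene total of each library, without TMM factors.

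The design, the alternatives, the rule for named genes and 23 gene lists were set before the data were examined. The lists cover VPS34 complexes, the autophagy core, selective autophagy and mitophagy, the RAB5 and RAB7 endosome cycle, Retromer and sorting nexins, lysosome, nuclear oxidative phosphorylation genes and mitochondrially encoded transcripts. They also cover the mitochondrial unfolded protein response, the integrated stress response, antioxidant genes, p53 targets, cholesterol synthesis, maternal effect genes, maternal mRNA decay, the meiotic spindle, and zygotic activation genes of the 2-cell stage. The remaining lists are housekeeping zygotic activation genes, ribosomal proteins, proteasome, glycolysis, cumulus and granulosa cell markers, and blood and immune cell markers. Lists with at least 3 tested genes were tested with camera (limma 3.58.1) against all other genes, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation.

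Named genes were Pik3c3 and, in each genotype comparison, genes with adjusted p under 0.05, a log2 fold change of at least 1 in size, at least 10 CPM in the higher group and no overlap between the groups. Where fewer than 20 genes passed the adjusted p alone, all of those with a symbol were named. For the change from GV to MII and the interaction, the 5 highest and 5 lowest were named by the same rule, without the overlap condition for the interaction. In each list, up to 4 members with the smallest adjusted p and at least 10 CPM in 1 group were named. A gene outside this rule is described as such. Gene positions are mm10 coordinates of GENCODE mouse release 21, matched by symbol for 53186 of the 55291 gene entries (96.2%).

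The ratio of gene to ERCC counts was compared between genotypes by exact two-sided permutation. Alternatives were size factors by the RLE method, ERCC totals as library sizes, DESeq2 1.42.0, no filter on low counts, a filter of 5 CPM in 3 libraries and a minimum log2 fold of 1. Further alternatives were mitochondrial genes left out, the replicate number as a block, all libraries in 1 fit, and each library left out in turn. Leaving called genes out of the lists, a covariate for the share of ribosomal RNA, the average of the genotype effect over both stages and the interaction lists with each library left out were added after the data were seen.

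The procedure was tested on simulated counts drawn from the libraries' own means and sizes. At GV (10657 genes) it recovered 44.1% of genes changed by 1 on the log2 scale and 94.9% of those changed by 2, and 9 of 144 calls (6.25%) were false. At MII (9413 genes) it recovered 37.5% and 91.5%, and 17 of 139 calls (12.2%) were false, above the nominal share. For the change from GV to MII (11166 genes) it recovered 37.1% and 89.5%, with 2 of 123 calls (1.63%) false. For the interaction (11330 genes) it recovered 8.25% and 55.7%, with 1 of 63 calls (1.59%) false. At GV, at MII and for the interaction the simulations called many more genes than the real data, which makes the adjusted threshold less strict. The noise of each gene was drawn on its own, without structure shared by libraries. These shares can therefore overstate what the real genotype comparisons recover. For the change from GV to MII the real comparison called far more genes, 7418 of 11607 in control, than the simulated 123. Its adjusted threshold was therefore less strict, and the simulated shares do not describe it. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.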

Results

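The transcriptomes of oocytes lacking VPS34 and of floxed control oocytes were compared at 2 stages, in fully grown GV oocytes before meiotic resumption and in ovulated MII oocytes. The series concerns VPS34 in the activation of the small GTPase RAB7, the placement of Retromer on autophagosomes and the removal of mitochondria by autophagy. Each of the 4 groups had 3 libraries of 5 oocytes (n = 3 per group throughout). Control GV libraries held 2956880, 3789990 and 4696630 gene counts, and cKO GV libraries 3214920, 3629490 and 3000700. Control MII libraries held 3668110, 3312760 and 3682570 and cKO MII libraries 2609780, 3303640 and 2805630, lower in cKO on average (exact permutation p = 0.1, the smallest that 3 against 3 can give). Libraries of 1 group differed by more than sampling noise, with a smallest chi-square of 5.38 per degree of freedom, and correlated at 0.934 to 0.977 across genes. A gene model that covers ribosomal RNA took 2.80%, 6.57% and 3.83% of gene counts in control GV libraries 1 to 3. In cKO GV libraries 1 to 3 it took 11.1%, 4.45% and 1.17%.

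The mRNA captured by Smart-seq2, relative to spike-in RNA, was compared first. Counts cannot tell the amount of an mRNA from how well it was captured, here or in the changes from GV to MII. The ratio of gene to ERCC counts was 6.68 ± 2.19 (SD) in control and 8.94 ± 3.65 in cKO GV oocytes, and 2.19 ± 0.302 in control and 1.92 ± 0.363 in cKO MII oocytes. The genotypes differed by 0.40 on the log2 scale at GV (exact p = 0.5) and by -0.20 at MII (exact p = 0.5), less than the spread between libraries. The GV difference was 0.12 without control 1, 0.09 without cKO 1 and 0.62 without control 3 or cKO 3. The MII difference was -0.04 without cKO 3, -0.13 without control 3 and -0.32 without control 1 or cKO 2. From GV to MII the mean log2 ratio fell by 1.56 in control and fell by 2.17 in cKO oocytes, 2.95-fold and 4.49-fold, with no overlap between stages in either genotype (exact p = 0.1 each). ERCC reads made up 13.8% ± 4.34 of all counts in control and 10.9% ± 3.42 in cKO GV libraries. In MII libraries their share was 31.5% ± 3.13 and 34.7% ± 4.58.

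**Figure D1:**
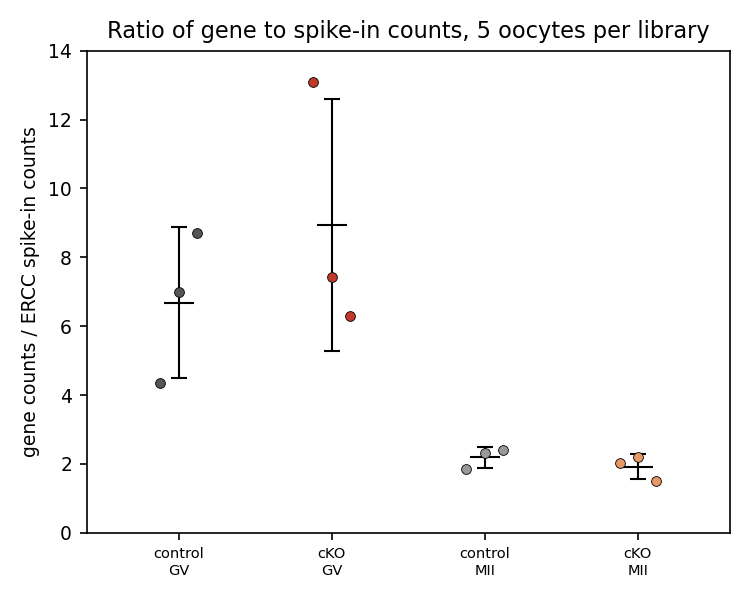
Ratio of gene counts to ERCC spike-in counts (vertical axis, linear from 0) in each library of 5 oocytes, by group. Points are libraries and bars the mean and SD (n = 3): GV ratios lie between 4.35 and 13.1 and MII ratios between 1.51 and 2.42, and the genotypes overlap at both stages.

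Deletion in GV oocytes was examined first for its target. Pik3c3 (chromosome 18, 30272747 to 30348126) stood at 1.96 ± 0.615 CPM (SD) in cKO and 30.01 ± 4.99 CPM in control GV oocytes, 15.7-fold lower (log2 fold change -3.97, SE 0.32, adjusted p = 1.5e-04, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). These counts cover the whole gene and had been seen when the columns were matched to genotypes. The largest fall was that of Manba, the lysosomal beta-mannosidase (chromosome 3, 135485611 to 135571404), from 47.1 ± 5.03 CPM in control to 0.736 ± 0.4003 CPM in cKO. It was 64.8-fold lower (log2 -6.02, SE 0.36, adjusted p = 1.1e-05). Spopl, a substrate adaptor of cullin-3 ubiquitin ligases (chromosome 2, 23506220 to 23572106), fell 8.98-fold from 34.3 ± 17.8 to 3.93 ± 0.789 CPM (adjusted p = 0.00732). Ldha, a subunit of lactate dehydrogenase (chromosome 7, 46841475 to 46855627), fell 5.66-fold from 17.97 ± 2.96 to 3.31 ± 0.942 CPM (adjusted p = 0.0107). Ccnd2, cyclin D2 (chromosome 6, 127125162 to 127152193), fell 3.44-fold from 110.3 ± 13.3 to 33.3 ± 6.58 CPM (adjusted p = 0.00732).

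Hormad1, a protein of the meiotic chromosome axis (chromosome 3, 95559677 to 95587671), fell 11.9-fold in cKO GV oocytes, from 7.51 ± 2.77 to 0.621 ± 0.350 CPM (adjusted p = 0.0256, edgeR). Rps3a3 (chromosome 13, 108670603 to 108671397), annotated as a processed pseudogene of the ribosomal protein gene Rps3a1, was 19.1-fold lower (log2 -4.26, SE 0.45, adjusted p = 0.00248). It shares sequence with Rps3a1 and its value is uncertain. Prr18 (chromosome 17, 8337459 to 8344113) rose 23.9-fold, from 0.585 ± 0.795 to 17.4 ± 9.58 CPM (log2 4.58, SE 0.68, adjusted p = 0.0256). Aimp1, a scaffold of the aminoacyl-tRNA synthetase complex (chromosome 3, 132660499 to 132684370), rose 3.75-fold, from 6.34 ± 0.968 to 24.9 ± 4.07 CPM (log2 1.91, SE 0.27, adjusted p = 0.0232).

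These 9 genes, 2 higher and 7 lower in cKO, were all that edgeR called among 10911 tested at GV. In all 240 genes (104 higher, 136 lower), 2.20% of those tested, had an unadjusted p under 0.05. That lies below the share of 0.05 that would be expected without any difference. DESeq2 called 13 genes, these 9 and Inha (adjusted p = 0.00400), Celf1 (0.0162), Gm4349 (0.0227) and Gm15361 (0.0496), the last 3 named after their values were seen. With ERCC totals as library sizes 11 genes were called, 6 higher and 5 lower (54.5% higher against 22.2%). That scaling moved the median of all genes to 0.46, and Ccnd2 (log2 -1.28, adjusted p = 0.727) and Ldha (log2 -2.10, adjusted p = 0.278) were not among the calls. With all 12 libraries in 1 fit only Pik3c3, Spopl and Aimp1 passed, and the adjusted p was 0.102 for Manba, 0.0771 for Rps3a3 and Ccnd2, 0.234 for Hormad1, 0.337 for Prr18 and 0.691 for Ldha. Pik3c3 and Manba passed with any 1 library left out. The count fell to 4 without control 2 and to 2 without cKO 2, and was 6 without control 1. Without cKO 2 the adjusted p was 0.0734 for Rps3a3, 0.124 for Spopl, Aimp1 and Ccnd2, 0.160 for Ldha and Prr18 and 0.376 for Hormad1. Without control 2 it was 0.0516 for Ccnd2 and Hormad1, 0.0625 for Ldha, 0.162 for Aimp1 and 0.198 for Prr18. Without control 1 it was 0.195 for Aimp1 and Hormad1 and 0.183 for Prr18. Without control 3 it was 0.0814 for Aimp1 and 0.125 for Hormad1, while the log2 fold change of Prr18 went to 6.53. Without cKO 1 it was 0.0544 for Hormad1.

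**Figure D2:**
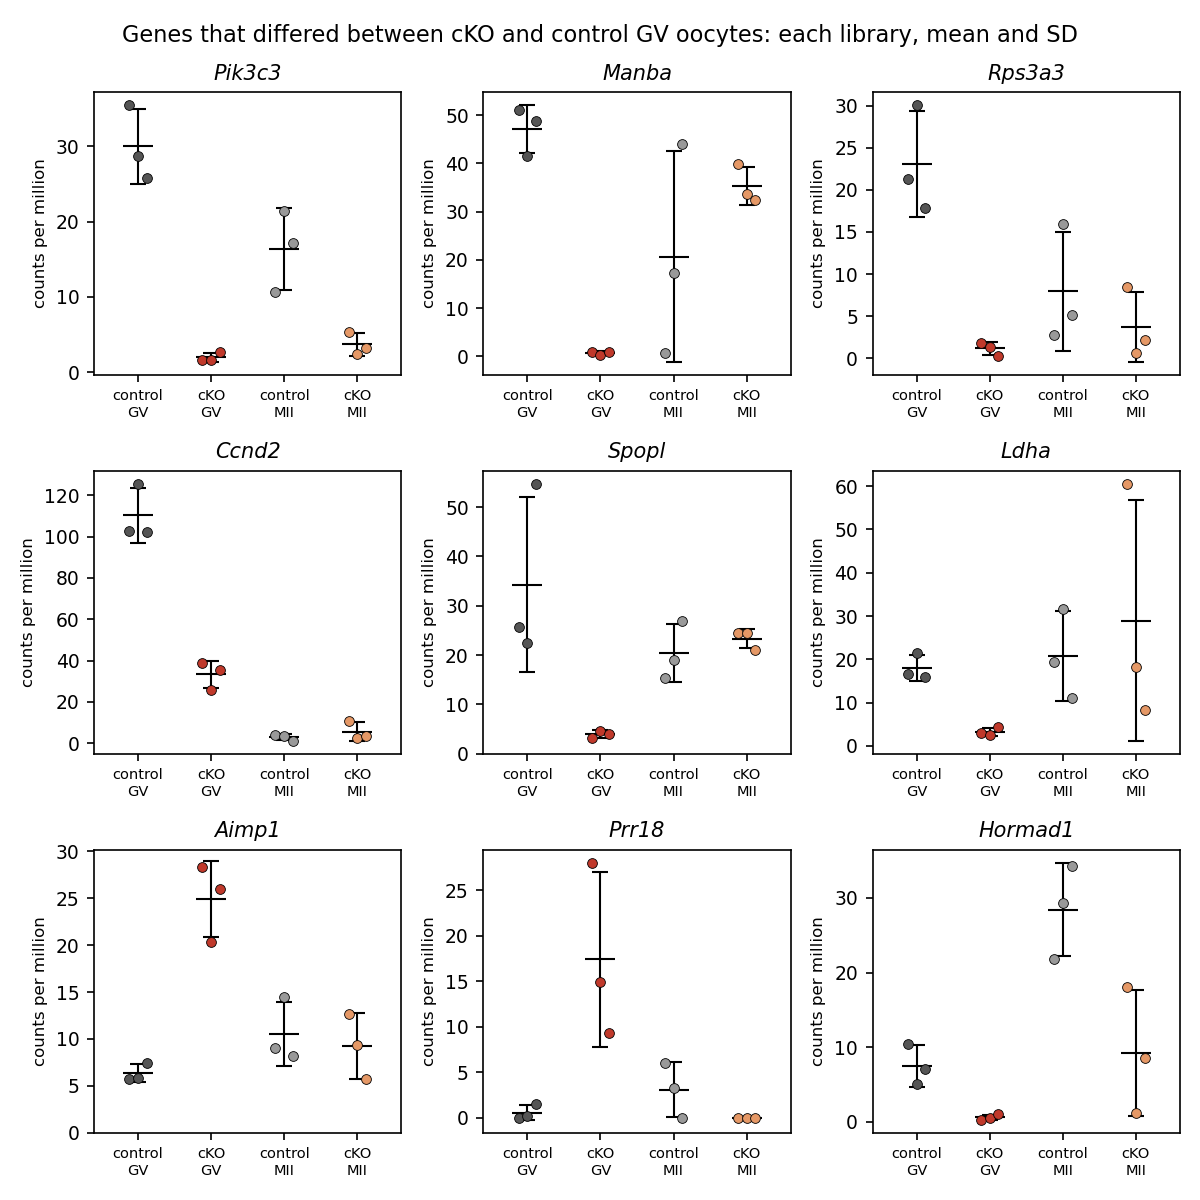
CPM per library (vertical axes, each panel with its own scale) of the 9 genes called between cKO and control GV oocytes. Points are GV and MII libraries by group and bars the mean and SD (n = 3). At GV cKO and control do not overlap in any panel, with Aimp1 and Prr18 higher and Pik3c3, Manba, Rps3a3, Ccnd2, Spopl, Ldha and Hormad1 lower in cKO. At MII the genotypes overlap in some panels, among them that of Manba.

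Genes that work with VPS34 showed no call at GV beyond Pik3c3 itself. In the VPS34 complexes 1 of 9 tested members fell, Pik3c3, and the others included Sh3glb1 at log2 0.32 (SE 0.24) and Vmp1 at -0.13 (SE 0.31). None of 24 autophagy core genes, 26 genes of selective autophagy and mitophagy, 28 genes of the RAB5 and RAB7 endosome cycle or 21 Retromer and sorting nexin genes was called. Among them Ulk1 stood at 0.55 (SE 0.33), Map1lc3a at 0.32 (SE 0.23), the mitofusin Mfn1 at 0.54 (SE 0.20), Rab7 at -0.31 (SE 0.22) and Snx3 at -0.33 (SE 0.19). The camera adjusted p of these lists was 0.952, 0.0644, 0.438 and 0.498.

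With the preset correlation camera called 9 of 22 tested lists at GV, each lower in cKO. Nuclear oxidative phosphorylation genes had a median log2 fold change of -0.10 with 54 of 72 negative (adjusted p = 0.00461; adjusted p = 0.442 with an estimated correlation), and Uqcrb stood at -0.44 (SE 0.19). Maternal effect and oocyte genes had a median of -0.14 with 30 of 41 negative (adjusted p = 0.00461; 0.442 as adjusted p with an estimated correlation). The zona pellucida gene Zp2 stood at -0.46 (SE 0.21) and Oosp1 at -0.45 (SE 0.23). Ribosomal proteins, whose counts are uncertain because of their many pseudogenes, had a median of -0.11 with 52 of 73 negative (adjusted p = 0.00742; 0.729 as adjusted p with an estimated correlation). Mitochondrially encoded transcripts had a median of -0.14 with 10 of 13 negative (adjusted p = 0.0382; 0.632 as adjusted p with an estimated correlation), and zygotic activation genes of the 2-cell stage a median of -0.20 with 5 of 6 negative (adjusted p = 0.00757; 0.334 as adjusted p with an estimated correlation). Cumulus and granulosa cell markers (adjusted p = 0.00393, median -0.03), VPS34 complexes (0.00396, median 0.0093), lysosome (0.00396, median 0.0048) and glycolysis (0.0118, median -0.06) rested on few members: Hsd17b1 at -2.43 (SE 0.44) and Inha at -1.32 (SE 0.23), then Pik3c3, Manba and Ldha. Their adjusted p with an estimated correlation was 0.237 for the first 3 and 0.442 for glycolysis. The means of the VPS34 complexes (-0.40) and of lysosome (-0.26) were negative like their test, unlike their medians.

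The ribosomal and the mitochondrially encoded lists also moved with the ribosomal RNA share of the libraries, by 0.54 and 0.60 between libraries above and below its median at GV. Maternal effect genes moved by 0.23 and oxidative phosphorylation genes by 0.17, both more in size than their medians between genotypes. With that share as a covariate, chosen after seeing the data, the medians of the first 2 lists were -0.31 and -0.38, and those of the other 2 -0.19 and -0.15. Without control 2 the ribosomal median turned to 0.06 (adjusted p = 0.366), and without cKO 3 the ribosomal and mitochondrially encoded medians turned to 0.07 (0.135) and 0.11 (0.248). Without cKO 1, the GV library with the highest share, they went the other way, to -0.24 (adjusted p = 6.0e-13) and -0.52 (6.1e-13).

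No GV list was called with an estimated correlation, and with ERCC totals as library sizes every list median at GV was positive, between 0.24 and 0.60. Without control 1 there were 5 calls (VPS34 complexes, lysosome, maternal effect, oxidative phosphorylation and ribosomal proteins), without control 2 there were 2 (VPS34 complexes and cumulus markers) and without cKO 3 there were 3 (cumulus markers, glycolysis and zygotic activation genes). Without cKO 1 or cKO 2 there were 7: the first lost glycolysis and zygotic activation genes, the second glycolysis and the mitochondrially encoded transcripts (adjusted p = 0.0887). Leaving the called genes out of the lists left 5, without VPS34 complexes, lysosome, glycolysis and the mitochondrially encoded transcripts. Adjusted over the list alone, 6 members were called at GV against 3 over all genes tested: Pik3c3, Manba and Ldha, and in addition Inha (5.5e-04), Hsd17b1 and Tcstv3 (log2 -0.89, 0.0158). Among lists without a call, genes of the integrated stress response had a median of 0.11 with 20 of 24 positive (adjusted p = 0.102), with Ddit3 at 0.22 (SE 0.18) and Ppp1r15a at 0.25 (SE 0.19). The adjusted p was 0.115 for antioxidant genes and for housekeeping zygotic activation genes, 0.222 for the mitochondrial unfolded protein response and for cholesterol synthesis, 0.335 for p53 targets, 0.401 for maternal mRNA decay, 0.498 for proteasome and 0.677 for the meiotic spindle. Named members were Gpx3 at -0.46 (SE 0.17), Rrp12 at 0.96 (SE 0.34), Scd2 at -1.78 (SE 0.47), Bax at 0.79 (SE 0.29), Cnot6 at 0.51 (SE 0.22) and Plk4 at -1.85 (SE 0.58). The direction of the test differed from that of the median for autophagy core, antioxidant genes and the spindle list. Of the blood and immune markers only C1qb (-0.20, SE 0.23) and 1 other gene were measured, too few for a test.

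In MII oocytes Pik3c3 stood at 3.66 ± 1.52 CPM in cKO and 16.4 ± 5.44 CPM in control, 4.57-fold lower (log2 -2.19, SE 0.39), which did not pass over all genes (adjusted p = 0.530, edgeR) but did when adjusted over the list alone (0.00134). DESeq2 gave -2.19 with an adjusted p of 0.0142. Manba, nearly absent from cKO GV oocytes, was at 39.9, 33.6 and 32.4 CPM in the cKO MII libraries and at 0.818, 17.2 and 44.0 CPM in the control MII libraries (log2 0.76, SE 0.86). Of the other genes called at GV, Hormad1 stood at -1.68 (SE 0.64), Rps3a3 at -1.14 (SE 0.83), Ccnd2 at 0.94 (SE 0.64), Ldha at 0.43 (SE 0.68), Spopl at 0.17 (SE 0.25) and Aimp1 at -0.22 (SE 0.37), none of them called at MII. Prr18, higher in cKO at GV, had too few counts to be tested at MII, with 22, 11 and 0 counts in the control libraries and 0 in each cKO library.

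edgeR called 0 of 9677 genes at MII, and it called 0 with any 1 library left out. At an unadjusted p under 0.05 there were 872 genes (345 higher, 527 lower), 9.01% of those tested. This share lay above 0.05, but genes are not independent replicates. DESeq2 called 4 genes, Pik3c3 and 3 others. Cyp11a1, the first enzyme of steroid synthesis and a member of the cumulus and granulosa marker list, stood at 4.11 (adjusted p = 0.00316). Its CPM was 26.4, 5.15 and 8.20 in cKO 1 to 3 and 0.818, 0 and 1.36 in control 1 to 3, and cKO 1 held the most RNA of cumulus markers of the MII libraries (2189 CPM). The other 2 were the meiotic gene Meioc at 2.45 (adjusted p = 0.0142) and Astl, the oocyte protease ovastacin, at -1.23 (adjusted p = 0.0246). Meioc was named after its value was seen. Without a filter on low counts edgeR called 96 genes, 28 higher and 68 lower. ERCC totals as library sizes moved the median of all genes to -0.15 and gave 0 calls.

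The ribosomal protein list was higher in cKO MII oocytes, with a median log2 fold change of 0.34 and 60 of 70 members positive (adjusted p = 4.3e-04; adjusted p = 0.776 with an estimated correlation). Rpl37a stood at 0.84 (SE 0.35), Rpl17 at 0.46 (SE 0.20) and Rps3a1 at 1.30 (SE 0.44), all uncertain as members of families with pseudogenes. Its value depended on cKO 1, the MII library with the most cumulus marker RNA, where the mean log2 CPM of the list was 5.21. It was 3.57 in control 1, the library with the next most marker RNA, and 4.78 in control 2. Summed cumulus and granulosa marker CPM was 2189 in cKO 1 against 1287 and 1011 in cKO 2 and 3 and 1614, 1469 and 1309 in the control MII libraries. At GV most of such a sum was Serpine2 (375 of 502 CPM in control, 372 of 477 CPM in cKO). Its share at MII is not given here, so the sum may follow Serpine2 more than the other markers. Without cKO 1 the ribosomal median was -0.08 (adjusted p = 0.883) and the cumulus marker median went from 0.69 to -0.20. Without control 2 these medians were 0.79 and 1.26, and without cKO 2 or cKO 3 the ribosomal median was 0.56. Maternal effect and oocyte genes were lower, with a median of -0.14 and 26 of 40 negative (adjusted p = 0.00751; adjusted p = 0.682 with an estimated correlation). Astl stood at -1.24 (SE 0.28), Zp1 at -0.60 (SE 0.17), the growth factor Gdf9 at -0.88 (SE 0.28) and Tle6 at -0.56 (SE 0.19). With ERCC totals as library sizes the median was 0.18 for ribosomal proteins and -0.30 for maternal effect genes.

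These 2 of 23 lists were called at MII, and neither with an estimated correlation. Without cKO 1 neither was called (maternal effect genes adjusted p = 0.134) and glycolysis was (0.00885). Without control 1 the ribosomal list was lost (median 0.12, adjusted p = 0.344) and without control 3 the maternal effect list (adjusted p = 0.0634). Oxidative phosphorylation genes were also called without control 2 (adjusted p = 0.00614), without cKO 2 (0.00176) and without cKO 3 (0.00437), and cumulus markers without cKO 2 (0.00762) and without cKO 3 (3.1e-06), which made 3, 4 and 4 calls. With all libraries, oxidative phosphorylation genes had a median of 0.18 (adjusted p = 0.0671), with Ndufa2 at 0.80 (SE 0.32). The adjusted p was 0.141 for cumulus markers, 0.248 for Retromer and sorting nexins (Snx6 at 0.75, SE 0.25) and for maternal mRNA decay (Pan3 at 0.73, SE 0.21), and 0.376 for housekeeping zygotic activation genes. For the VPS34 complexes it was 0.567 (Becn1 at -0.69, SE 0.30), for the RAB5 and RAB7 cycle 0.564 (Rab7 at -0.38, SE 0.19), for autophagy core 0.659 and for the integrated stress response 0.550 (Slc3a2 at -0.54, SE 0.18). Of the spindle list (Kif20a at -0.75, SE 0.23; Mos at -0.53, SE 0.17) the median was -0.12. Adjusted over the list alone, 3 members were called, Pik3c3, Atg16l1 of the autophagy core (-0.87, SE 0.19; 0.0151) and the cumulus marker Cyp11a1 (0.0113), against 0 over all genes. Median, mean and test differed in sign for VPS34 complexes, lysosome, mitochondrially encoded transcripts, mitochondrial unfolded protein response, antioxidant genes, p53 targets and proteasome.

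Whether the same genes differed at both stages was asked over 9088 genes tested at each. Of these, edgeR called 8 at GV and 0 at MII, with 0 shared. DESeq2 called 12 and 3, and shared 1, Pik3c3, against 0.00396 expected (Fisher's exact p = 0.00396). Pik3c3 is the deleted gene, and its counts had been seen when the columns were matched to genotypes. That p-value therefore says nothing about other genes, none of which was shared. The genotype differences at GV and MII were unrelated across genes, which are not independent replicates (Spearman's rho 0.0155).

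The change from GV to MII was large in both genotypes. Summed cumulus and granulosa marker CPM went from 502 to 1464 in control and from 477 to 1496 in cKO. At GV most of this sum was Serpine2 (375 CPM in control, 372 CPM in cKO), which rose to MII in both genotypes. The genes that rose below include genes of the cumulus matrix. RNA of cumulus cells in the MII libraries is therefore a possible source of these rises, which was not tested. They are changes of the libraries and need not be changes of the oocyte. Among genes that rose, Tnfaip6, a component of the expanding cumulus matrix, went from 0 counts to at least 247.2-fold higher in control and at least 260.8-fold higher in cKO libraries (floor of 3 counts over the group). Lox, lysyl oxidase, rose at least 97.7-fold in control and at least 142-fold in cKO, and Ptx3, another cumulus matrix protein, at least 37.9-fold and at least 49.7-fold. Akr1c18 rose at least 74.8-fold in control and Ier3 at least 72.3-fold in cKO. Spp1, osteopontin, rose by 9.55 on the log2 scale (SE 0.83) in control and by 10.65 (SE 0.88) in cKO. Among genes that fell, uridine phosphorylase Upp1 went from 389.8 ± 51.5 to 2.27 ± 1.26 CPM in control (log2 -7.27, SE 0.30) and from 333.2 ± 52.5 to 1.97 ± 0.767 CPM in cKO (log2 -7.24, SE 0.31). Gstt2 (log2 -6.54, SE 0.45), brain-type creatine kinase Ckb (-6.05, SE 0.33) and Rpl7a (-6.05, SE 0.65, uncertain as a family with pseudogenes) fell in control. Iqcf1 fell by a ratio of 109.96 in control (95% counting interval 30.1 to 913.2) and 190.4 in cKO (33.8 to 7555). Prr18, Zfp524 and Ttll10 fell at least 50.8-fold, 38.4-fold and 35.4-fold in cKO.

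Each of these changes passed edgeR's test in the genotype named. In control the call of Ptx3 was lost without control MII 1 (adjusted p = 0.0622), and the log2 change of Gstt2 was -7.17 without control MII 3. In cKO the call of Ptx3 was lost without cKO GV 1 (adjusted p = 0.0557) or cKO GV 3 (0.0612). Without cKO MII 1 the bounds in cKO were 99.9-fold for Tnfaip6, 41.4-fold for Ier3 and 10.2-fold for Ptx3, the log2 change of Spp1 was 9.94, and Iqcf1 had 0 counts. The bound of Ptx3 was 77.0-fold without cKO MII 2.

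Of 11607 genes tested, edgeR called 7418 in control (3490 higher and 3928 lower at MII) and 7371 in cKO oocytes (3422 higher, 3949 lower). Of these, 6366 were called in the same direction in both genotypes, 2 in opposite directions, 1050 in control alone and 1003 in cKO alone, groups that are not tests of a difference. The changes correlated at 0.924 across genes, and for 90.1% of genes they differed by less than 1 on the log2 scale. These directions are relative to the total mRNA captured. With ERCC totals as library sizes the median of all genes moved to -1.72 in control and -2.37 in cKO. On that scale 8206 genes were called in control (65 higher, 8141 lower) and 10302 in cKO (93 higher, 10209 lower).

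**Figure D3:**
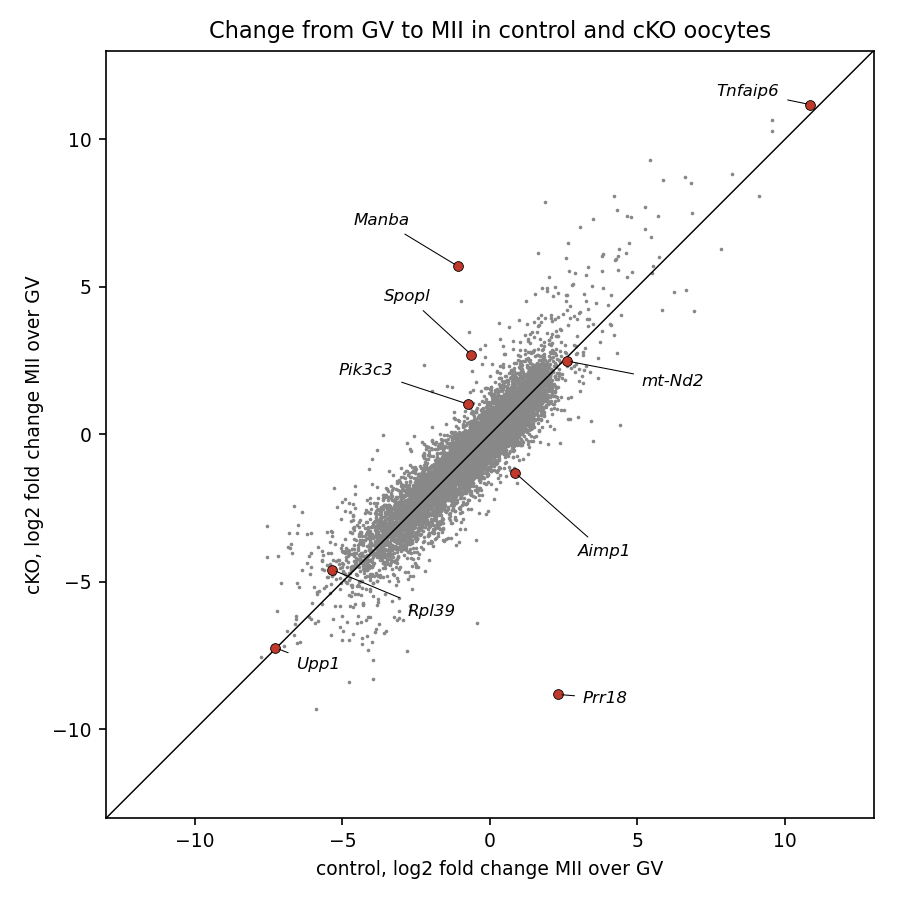
Log2 fold change from GV to MII in control (horizontal axis) and cKO oocytes (vertical axis) for the 11607 genes tested, with the line of equal change. Labelled genes lie near the line (Upp1, Rpl39, mt-Nd2) or away from it (Spopl, Manba, Pik3c3, Aimp1, Prr18); Tnfaip6 and Prr18 have a group at 0 counts, so their plotted values depend on the prior count. With ERCC totals as library sizes most of the genes called were lower at MII (8141 of 8206 in control, 10209 of 10302 in cKO).

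Transcripts of the respiratory chain and of the ribosome fell from GV to MII. Of 72 nuclear oxidative phosphorylation genes 64 fell and 3 rose in each genotype, with a median log2 change of -2.77 in control and -2.28 in cKO (adjusted p = 4.3e-24 and 1.6e-19; adjusted p = 0.317 and 0.244 with an estimated correlation). The ATP synthase subunit Atp5e fell by 4.81 (SE 0.26) in control and fell by 4.13 (SE 0.25) in cKO. Of 73 ribosomal protein genes, uncertain as above, 69 fell in control (median -2.87) and 67 in cKO (median -2.51; adjusted p = 3.8e-17 and 1.8e-12; adjusted p = 0.434 and 0.541 with an estimated correlation). Rpl39 stood at -5.35 (SE 0.36) and -4.59 (SE 0.35). The 13 mitochondrially encoded transcripts went the other way, with 12 higher in each genotype and medians of 1.69 and 1.72, which turned to -0.05 and -0.80 with ERCC totals (adjusted p = 4.8e-04 and 1.2e-04; adjusted p = 0.535 and 0.541 with an estimated correlation). Complex I subunit mt-Nd2 stood at 2.60 (SE 0.35) and 2.48 (SE 0.35).

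Maternal effect and oocyte genes fell, with 20 of 41 lower in control and 24 in cKO, and 4 and 5 higher (medians -0.67 and -0.86; adjusted p = 8.8e-06 and 2.2e-06; adjusted p = 0.372 and 0.244 with an estimated correlation). Zp2 fell by 4.54 (SE 0.22) in control and fell by 4.04 (SE 0.22) in cKO, and Zp3 stood at -4.78 and -4.71 (SE 0.25 each). Of 31 proteasome genes 19 and 20 fell, among them Psmb1 at -3.75 and -3.51 (SE 0.22 each), with medians of -0.995 and -1.31 (adjusted p = 4.0e-04 and 2.3e-04; adjusted p = 0.434 and 0.479 with an estimated correlation). Genes of maternal mRNA decay and translation control rose, 21 of 38 in control and 22 in cKO, with 7 and 5 lower. Their medians of 0.75 and 0.74 turned to -0.996 and -1.64 with ERCC totals (adjusted p = 0.0154 and 0.00653; adjusted p = 0.372 and 0.244 with an estimated correlation). The translational regulator Cpeb4 stood at 1.73 and 1.70 (SE 0.21 each) and Ybx2, which binds stored mRNA, at -3.83 (SE 0.35) and -4.17 (SE 0.36). Cumulus and granulosa cell markers rose, 11 of 17 in control and 14 in cKO, with medians of 2.37 and 2.88 (adjusted p = 0.0141 and 0.00181; adjusted p = 0.597 and 0.547 with an estimated correlation), and their medians were 0.70 and 0.64 with ERCC totals. These medians did not move when the 2 members with a group at 3 counts or fewer were put at their bound. Serpine2 stood at 1.74 and 1.51 (SE 0.22 each) and prostaglandin synthase Ptgs2 at 4.82 (SE 0.80) and 5.49 (SE 0.70). The list of the mitochondrial unfolded protein response and dynamics was called in cKO alone, with 12 of 23 lower (median -0.9998, adjusted p = 0.0371; adjusted p = 0.479 with an estimated correlation), against 13 lower in control (median -0.86, adjusted p = 0.0805). Timm17a fell by 4.85 (SE 0.24) in control and fell by 4.51 (SE 0.24) in cKO.

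**Figure D4:**
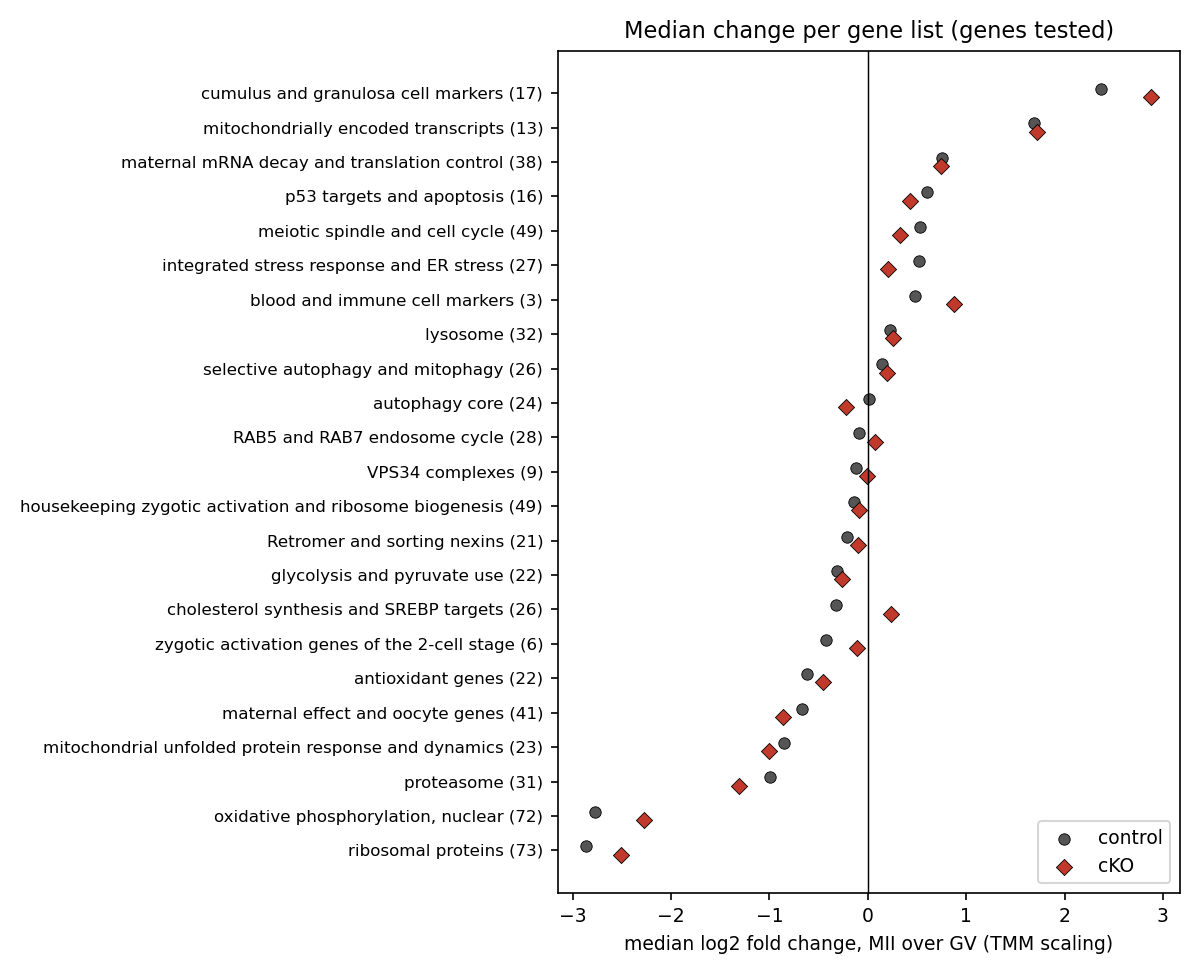
Median log2 fold change from GV to MII (horizontal axis) of the members of the 23 gene lists in control and cKO oocytes, TMM scaling. Ribosomal proteins (-2.87 and -2.51) and nuclear oxidative phosphorylation genes (-2.77 and -2.28) lie lowest and cumulus markers (2.37 and 2.88) highest; with ERCC totals as library sizes the medians of mitochondrially encoded transcripts (-0.05 and -0.80) and maternal mRNA decay (-0.996 and -1.64) turn negative.

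Lists without a call in either genotype held members that moved both ways. Of 49 spindle and cell cycle genes 24 rose and 12 fell in control, and the kinase Cdk1 fell by 5.50 (SE 0.33) in control and fell by 4.84 (SE 0.32) in cKO. Of 24 autophagy core genes 6 rose and 8 fell in control. Map1lc3a fell by 3.47 (SE 0.31) in cKO, and Rb1cc1 rose by 1.44 (SE 0.19) in control. Of 26 genes of selective autophagy and mitophagy 10 rose and 10 fell in control, with the mitophagy receptor Bnip3 at 2.25 (SE 0.29) and 2.36 (SE 0.30) and the ubiquitin ligase Mul1 at -4.26 (SE 0.38) and -4.61 (SE 0.39). Of 28 genes of the RAB5 and RAB7 cycle 9 rose and 8 fell, with Mon1a, part of the RAB7 exchange factor, at -5.62 (SE 0.38) and -4.60 (SE 0.35). Counts in control were 3 higher and 4 lower of 9 for VPS34 complexes, 6 and 9 of 21 for Retromer, 11 and 10 of 32 for lysosome, 13 and 6 of 27 for the integrated stress response, 4 and 10 of 22 for antioxidant genes and 8 and 1 of 16 for p53 targets. They were 9 and 9 of 26 for cholesterol synthesis, 0 and 2 of 6 for zygotic activation genes, 20 and 18 of 49 for housekeeping zygotic activation genes, 3 and 8 of 22 for glycolysis and 1 and 1 of 3 for blood and immune markers. With ERCC totals the median of each of these lists was negative in both genotypes. In all lists 498 members were called in each genotype, and 500 in each when adjusted over the list alone. Median, mean and test differed in sign in control for VPS34 complexes, autophagy core, selective autophagy, the RAB cycle, lysosome, cholesterol synthesis and blood markers. In cKO they did so for VPS34 complexes, selective autophagy, the RAB cycle, Retromer, the integrated stress response and blood markers.

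Whether the change from GV to MII differed between genotypes was tested directly. Spopl was the 1 gene called: its change was 3.32 higher on the log2 scale in cKO than in control (SE 0.48, adjusted p = 0.0168, edgeR interaction test). The differences of the other genes called at GV did not pass: Manba 6.77 (SE 1.24, adjusted p = 0.355), Aimp1 -2.14 (SE 0.46, 0.355), Ccnd2 2.70 (SE 0.60, 0.506), Ldha 2.91 (SE 0.80, 0.875), Rps3a3 3.10 (SE 1.07, 0.875) and Hormad1 1.87 (SE 0.96, 0.875). Prr18, at 0 counts in cKO MII oocytes, did not pass either (0.355). That of Pik3c3 was 1.76 (SE 0.53, adjusted p = 0.875, and called when adjusted over the list alone, as was Manba). In all 608 of 11607 genes (264 higher, 344 lower), 5.24%, had an unadjusted p under 0.05, near the share expected without any difference. DESeq2 called 5 genes, Spopl, Manba, Ccnd2, Aimp1 and Speer4a.

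The call of Spopl was lost with ERCC totals (2.89, adjusted p = 0.0899) and without cKO GV 1 (adjusted p = 0.0568), cKO GV 2 (0.0736), control MII 2 (0.0721), cKO MII 2 (0.0757) or cKO MII 3 (0.0594), each of which left 0 calls except ERCC totals, which gave 3 other genes and moved the median of all genes to -0.61. There were 2 calls without control GV 3 or control MII 1 and 3 without control MII 3. Ribosomal proteins (median difference 0.43, 66 of 73 positive, adjusted p = 1.8e-07; adjusted p = 0.890 with an estimated correlation) and oxidative phosphorylation genes (0.25, 58 of 72 positive, adjusted p = 1.1e-04; adjusted p = 0.890 with an estimated correlation) fell less in cKO than in control by the preset test, and their median differences turned to -0.26 and -0.35 with ERCC totals. Leaving each library out of this test was added after the data were seen. Without cKO MII 1, the library with the most cumulus marker RNA, the median differences were -0.02 and 0.05 (adjusted p = 0.712 for both), and without cKO GV 3 they were 0.24 and 0.22 (0.0548 for both). Both lists were called with any other library left out, the ribosomal median then lying between 0.17 (without control MII 1) and 0.90 (without control MII 2). Named members were Rpl17 at 0.73 (SE 0.28) and Cox7b at 1.25 (SE 0.44). With all libraries in the fit the other 21 lists were not called, with the smallest adjusted p at 0.126 for the integrated stress response (median -0.27). Cumulus and granulosa cell markers had a median difference of 0.63 with 13 of 17 positive (camera adjusted p = 0.192).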

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

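Some tests in this part were chosen only after the result they concern had been seen. They are those of chromosome 3, the Rps3a family, the GV genes at MII and the level of the ribosomal list at MII. The tests of the median, the signs and the spread of the cumulus markers at GV were also among them. The splits and relabellings of libraries and the tests by edgeR and camera were planned.

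Spopl drew attention because the genotype difference changed between stages, as tested by the interaction. Its transcript was 8.98-fold lower in cKO GV oocytes and stood at 0.17 on the log2 scale at MII (SE 0.25), and the difference between stages was 3.32 (SE 0.48, adjusted p = 0.0168, edgeR). With genotype relabelled within each stage, 15 of 100 relabellings, the real one included, gave as many genes as the 1 called here, and the highest other gave 50, so chance is not excluded for this count. Shmt2, a mitochondrial enzyme of 1-carbon metabolism, drew attention because its direction was opposite in every library at the 2 stages. CPM was 40.2, 31.7 and 46.6 in control and 48.8, 51.2 and 47.7 in cKO GV libraries, and lower in every cKO library at MII (log2 -0.40, SE 0.19, adjusted p = 0.558, edgeR). That separation was not tested, it was found among 183 genes looked at, and with TMM scaling the GV groups overlap. The interaction test gave -0.68 (SE 0.29, adjusted p = 0.875).

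For the 9 genes called at GV the 10 splits of 6 libraries are too few for a share under 0.05: 2 of them, the real one included, called at least 9 genes, and the highest other called 1037. That split set control 1, control 3 and cKO 3 against control 2, cKO 1 and cKO 2, which is the division by ribosomal RNA share and points to a structure of the samples other than genotype.

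Explanations of the genes called at GV were then weighed. Beyond Pik3c3, 3 of them lie on chromosome 3 (Manba, Aimp1 and Hormad1), where 23 of 510 genes had an unadjusted p under 0.05 against 11.2 expected (odds ratio 2.22, Fisher's exact adjusted p = 0.0190). With the called genes left out, a change made after that value was seen, it was 20 of 507 (odds ratio 1.99, 95% interval 1.18 to 3.19, Fisher's exact p = 0.00653, adjusted p = 0.131 over 20 chromosomes), so whether sequence variants differ between the mice stays open. On this measure chromosome 3 did not stand out from chromosome X (odds ratio 2.02, Fisher's exact p = 0.0197, adjusted p = 0.197). Chromosome 18, which holds Pik3c3, had an odds ratio of 1.95 (Fisher's exact p = 0.0519, adjusted p = 0.346). Chromosome 3 was picked after its called genes had been noticed, and 2 limits on p were looked at. At MII its odds ratio was 1.28 (Fisher's exact p = 0.119). Manba and Aimp1 did not keep their difference at MII (log2 0.76 and -0.22), while Hormad1 and its neighbour Gm4349 kept their direction (-1.68 and -1.38). For Rps3a3 the parent gene Rps3a1 was higher in cKO at GV (log2 0.52, SE 0.22). The summed CPM of the family moved by 0.03 on the log2 scale, as shared reads assigned differently would give. The copies Rps3a2 and Rps3a3 took on average 32.4% of it in control and 2.67% in cKO at GV. At MII they took 38.8% and 9.75%, without overlap between genotypes at either stage (exact permutation p = 0.1 each). The family sum moved by 0.73 at MII (exact permutation p = 0.5). Whether the loss of Pik3c3 changed the others called at GV cannot be told apart from these explanations: the 7 genes measured at MII had a mean log2 fold change, signed by their GV direction, of 0.0419 (SD 0.987, exact sign-flip p = 0.938).

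The higher ribosomal protein list at MII was weighed next. Without cKO 1, the library with 2189 CPM of cumulus markers, its median went from 0.34 to -0.0754 (adjusted p = 0.883), which would follow whatever made that library high. Over the 6 libraries the level of the list and the cumulus marker CPM had a Spearman's rho of 0.257 (exact permutation p = 0.658), so RNA of cumulus cells stays open as an explanation. That marker CPM is a sum that at GV was mostly Serpine2. An effect of the loss of Pik3c3 stays open: camera gave p = 0.483 with an estimated correlation, and the mean log2 CPM of the list was 0.37 higher in cKO (SE 0.52, exact p = 0.5). The 10 splits are too few for a share under 0.05: 7 gave at least the 2 lists called, and the highest other gave 7.

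The lower cumulus and granulosa marker list at GV was weighed last. Its median was -0.0343 with 7 of 9 markers negative, and Hsd17b1 (log2 -2.43) and Inha (-1.32) stood apart from Serpine2 (-0.07) and Cyp19a1 (0.07). A loss of cumulus cells large enough for Inha would have lowered the markers together. They moved apart by more than their errors allow (Cochran's Q 52.2 over 9 markers), and their median lay 1.29 above Inha (SD of the markers 0.923). Q and the SD include Inha and Hsd17b1, picked as the lowest, so this spread partly restates the choice. The other markers lay between -0.42 (Hsd3b1) and 0.65 (Inhba), which argues against such a loss as the reason for Inha and Hsd17b1. That holds only if the reads of these markers came from cumulus cells, which was not checked. A smaller loss cannot be told apart from none, since the median lay near 0. For the lists at GV the 10 splits are too few for a share under 0.05, and 1, the real one with 9 lists, gave as many, the highest other giving 4.

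For the other comparisons the 10 splits are too few for a share under 0.05. At MII edgeR called 0 genes in the real split (872 at an unadjusted p under 0.05, 4 called by DESeq2), so that all 10 gave as many, with 0 as the highest other. From GV to MII the real split called 7418 genes in control and 7371 in cKO, 1 split giving as many in each, and the highest other called 0.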

How the results depend on the processing

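The alternatives with the ribosomal RNA covariate, the lists without called genes, the average over stages and the interaction lists with 1 library left out were chosen after seeing the data. No log2 fold change of Pik3c3 or of the genes named by rule changed sign in the settings run for them, other list members were not run 1 by 1, and list medians and the balance of GV calls turned with ERCC totals as the report gives. List medians also turned with 1 library left out. Of the alternatives for results that answer a comparison 125 left them as they were, 31 moved a count and 1 made a result pass. For named genes and the average over stages 511 left them as they were, 37 lost a call and 9 moved a count. In these tallies a count near the main one passed as left, whatever its genes or directions, and the ERCC ratio was judged by its sign alone. Calls from GV to MII with ERCC totals therefore passed as left, although nearly all of them were lower at MII. The cause of a moved count or lost call was not tested, except where fewer genes or libraries entered. Genes called at GV were 28 without a filter, 3 with all libraries in 1 fit and 21 with the covariate, picked after the split with 1037 calls. Genes called at MII were 4 by DESeq2 and 96 without a filter. DESeq2 gave Pik3c3 at MII a log2 fold change of -2.19, past the threshold, and an overlap between stages of 1. The interaction gave 3 genes with ERCC totals, 5 by DESeq2 and 18 without a filter. Lists called were 0 at each stage with an estimated correlation, 5 at GV without called genes and 1 at MII with the covariate. With 1 library left out, genes called ranged from 2 to 10 at GV, 6788 to 7703 in control and 6670 to 7686 in cKO from GV to MII and 0 to 3 for the interaction, and lists from 2 to 9 at GV and 1 to 4 at MII. Pik3c3 ranged from -4.20 to -3.86 at GV and -2.54 to -1.94 at MII. A replicate block gave 11 genes at GV, 0 at MII and 1 for the interaction, and 3 lists at MII, with cumulus markers added (adjusted p = 0.0162, camera). A filter at 5 CPM added oxidative phosphorylation genes at MII (adjusted p = 0.0499). Libraries share only a number: correlations of same-numbered GV libraries were -0.23, 0.0059 and 0.21. Results on 2-cell embryos were not run. Simulated 2-fold changes were recovered at 44.1% for GV and 37.5% for MII, in simulations that called many more genes than the real comparisons.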

Other observations

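The average over stages, the genes named here and the test of transcript clearance were chosen after the data had been seen.

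Averaged over both stages, 5 of 11607 genes differed between genotypes (edgeR). Pik3c3 was lower in cKO (log2 -3.09, SE 0.25, adjusted p = 2.4e-06), as were Hormad1 (-2.63, SE 0.46, adjusted p = 0.0488), Spopl (-1.50, SE 0.24, adjusted p = 0.0208) and Gm4349 (-1.85, SE 0.28, adjusted p = 0.0161), a predicted gene. The average of Spopl stands for a difference at GV (-3.17) and not at MII (0.17). Meioc, needed for meiotic prophase, was higher (1.89, SE 0.32, adjusted p = 0.0329). The count was 9 with ERCC totals, 10 by DESeq2 and 18 without a filter. It was 3 without control GV 2 or cKO GV 1, 2 without control MII 3 or cKO MII 2, and 1 without cKO GV 2 or cKO MII 3.

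The metallothionein gene Mt1 was higher in every cKO library at both stages without passing. It was picked after its values had been seen, and how many other genes separate alike is not given here. With 3 libraries per group and 9088 genes tested at both stages, some would do so without any difference. At GV it stood at 5.07, 3.43 and 56.8 CPM in control and 394.4, 438.9 and 299.3 CPM in cKO (log2 4.01, SE 0.94, adjusted p = 0.999993, edgeR). At MII it stood at 8.45, 33.5 and 15.2 CPM in control and 54.03, 69.3 and 37.1 CPM in cKO (log2 1.48, SE 0.41, adjusted p = 0.530).

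A hypothesis was that cKO oocytes clear maternal transcripts less completely during maturation. Sets of transcripts that fall from GV to MII were chosen from each of the 6 MII libraries in turn, and the shift between genotypes was measured in the other 5. The mean shift was 0.018 on the log2 scale, with a range of -0.0825 to 0.0795, 4 of 6 shifts positive and a smallest exact p of 0.4, against an SD of 0.118 over regroupings. With 3 libraries per group a shift of this size cannot be told apart from none.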
